A study of Mus musculus with 3 samples.

How the data were processed

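The series holds 3 libraries from E14 cells, a mouse embryonic stem cell line: a ChIRP library of L1 RNA, a ChIRP library of Malat1 RNA and an input DNA library, each with 1 replicate. ChIRP (chromatin isolation by RNA purification) captures an RNA with biotinylated DNA probes and recovers the chromatin crosslinked to it. Per the labels' protocols, the probes were 59 nt long, cells were crosslinked with UV, formaldehyde and DSP, chromatin was sonicated to 2 to 5 kb, and libraries were amplified for 15 cycles. The sample labels name genomic DNA as the molecule of the L1 library, whereas the protocol text describes reverse transcription of retrieved RNA, so which nucleic acid was sequenced is not settled by the labels. Which part of the L1 sequence the probes match is not given in the sources used here.

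Only the L1 library was analysed, from 1 deposited peak list. The Malat1 and input libraries were not analysed here, so no comparison between RNAs, or with input, could be made. The peak list deposited by the authors has 3 columns, the chromosome, start and end of each peak, and gives no height, fold, p-value or score per peak. CASAVA, Bowtie2 2.2.2 and MACS 1.4.2 and the mouse build mm9 are named in the submitters' processing notes, without their roles or settings. The name of the deposited list carries the value 0.01 and an FDR of 5, which may be thresholds for calling or filtering peaks, but their meaning and unit are not stated. Whether the input library served as the control for peak calling, how reads that map to many places were treated, and the read depth are not given in the sources used here. A region without a peak may therefore hold signal below detection, and the treatment of reads from repeats can add or remove peaks at near-identical L1 copies. Sequence names such as those of unplaced sequence ending in random are those of mm9.

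All values below were computed from the peak positions with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Positions are printed from 1. Chromosomes 1 to 19, X and Y were analysed, and unplaced sequence was kept apart because its pieces have no known order. Density is the number of peaks per Mb of span, from the first peak's start to the last peak's end, since chromosome lengths of mm9 were not used here. Assembly gaps inside a span were not removed. Bins of 1 Mb run from the bin of the first peak to that of the last, and a peak belongs to the bin of its midpoint. The interval of a density or a ratio of densities is a 95% block bootstrap interval (10000 draws of blocks of 5 Mb). It describes how unevenly the peaks lie along the sequence, not the error between replicates, which 1 library cannot give. Clustering was set against 1000 random placements of the same peaks, with their widths in random order, no overlap and the same span on each chromosome (100 placements where covered bases were counted). A value is given with the lowest and highest of these placements, as a description of this peak list, and no p-value is printed. Shares have exact (Clopper-Pearson) 95% binomial intervals, which treat peaks as independent and so cover counting error only. The 95% bootstrap intervals of median width and of the width excess (2000 draws) resample single peaks and have the same limit. On simulated data, random placements of the real widths lay within their own central 95% in 37 of 40 runs, and peak sets in which 10% of peaks had been moved next to another lay above every placement in 40 of 40. The block interval held a simulated X to autosome ratio of 2 in 37 of 40 runs with uniformly placed peaks, and the bootstrap interval of the width excess held a simulated value of 2 in 37 of 40. The real peaks are clustered, so these runs do not show how often the intervals hold on such data.

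The rule for named items was fixed before the data were examined. It named the 5 bins with the most peaks, the 10 peaks with the highest score, and genes by their peaks. The file has no score, so no peak was named by it. No genome or annotation of mm9 was used here, and coordinates were not converted between builds, so the planned comparisons with gene bodies, exons, start sites, GC content, masked repeats, gene density and fixed gene lists were not run. Long peak-rich and peak-free stretches were named by length, a rule chosen after their values were seen. The alternatives tried were covered bases in place of peaks, another bin size and distance, merging of neighbouring peaks, placements within windows of 5 Mb, and several added later that are given in the closing section.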

Results

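The L1 RNA ChIRP library of E14 mouse embryonic stem cells yielded 24666 peaks, which together covered 161 Mb of the genome. L1 (long interspersed element 1) is a family of retrotransposons that makes up much of the repeat content of the mouse genome, and its transcripts are found in embryonic stem cells. The series set ChIRP of L1 RNA beside ChIRP of Malat1, a nuclear long noncoding RNA. Whether DNA or RNA was sequenced for the L1 library is not settled by the labels, so a peak need not be a site bound by L1 RNA. The Malat1 and input libraries were not analysed here, so the values describe where the L1 peaks lie and how they are spaced. Of the peaks, 24202 lay on chromosomes 1 to 19, X and Y and 464 on unplaced sequence. The read depth behind the peaks is unknown. There was 1 library and no replicate, so none of the differences could be set against the spread between replicates.

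Peaks were broad. Their median width on the assembled chromosomes was 6351 bp, with quartiles of 4095 and 8047 bp and a range from 566 to 41011 bp. The distribution had a mode between 6 and 7.5 kb, where 5747 of 24202 peaks lay (23.7%, 95% binomial interval 23.2 to 24.3). The class from 6.5 to 7 kb held the most peaks, 2241, against 1149 in the class from 5.5 to 6 kb and 1350 in that from 7.5 to 8 kb. Linear interpolation from the 500 bp on either side gave 3749 peaks for the 6 to 7.5 kb range, so the observed number was 1.53 times higher (95% bootstrap interval 1.46 to 1.61). The ratio exceeded 1 on 20 of 20 chromosomes (1 to 19 and X), from 1.25 on chromosome 17 to 2.10 on chromosome 18. This width range was not planned before the data were examined, and neither the interval nor this count covers the choice of its limits. Peaks wider than 10 kb numbered 2812, or 11.6%. The median and the mode lie above the 2 to 5 kb to which the chromatin was sonicated, and the caller's settings, which also shape widths, are not given in the sources used here.

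**Figure D1:**
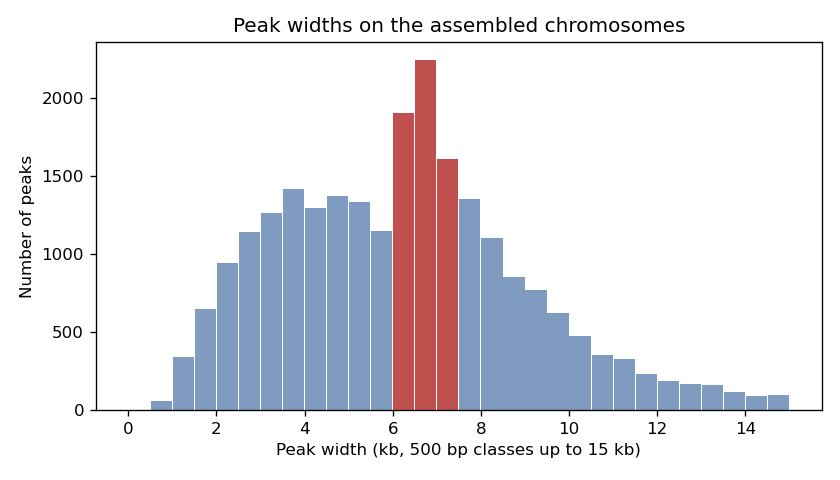
Number of peaks (vertical axis) by peak width in kb (horizontal axis, 500 bp classes up to 15 kb) on the assembled chromosomes, with the 6 to 7.5 kb classes in red. The class from 6.5 to 7 kb is the highest, with 2241 peaks.

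L1 peaks were denser on chromosome X than on the pooled autosomes, and among chromosomes 1 to 19 and X the highest value was that of X and the lowest were those of chromosomes 11 and 19. The X chromosome, known to be rich in L1 sequence, held 2177 peaks, or 13.3 per Mb of span (95% block interval 11.8 to 14.7). The 19 autosomes together held 9.13 peaks per Mb, which made X 1.46 times denser (95% block interval 1.29 to 1.65). Chromosome 11, known as one of the most gene-dense mouse chromosomes, held 618 peaks, or 5.20 per Mb (3.49 to 7.09). Chromosome 19 held 372 peaks, or 6.38 per Mb (4.12 to 8.55). The difference between chromosomes 19 and 11, 1.18 peaks per Mb, had an interval from -1.77 to 3.91, so these 2 could not be ordered. Chromosome 9, next with 7.71 per Mb, was not separated from chromosome 19 (difference 1.32, -1.66 to 4.57) or from chromosome 11 (2.50, -0.29 to 5.30).

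Among the autosomes, density ranged from 5.20 to 12.6 peaks per Mb, with a median of 8.86 on chromosome 10. Chromosome 3 came closest to X with 1964 peaks, or 12.6 per Mb (10.7 to 14.5), followed by chromosome 1 with 2123 peaks, or 10.9 per Mb (8.90 to 12.9). The difference between X and chromosome 3 was 0.78 peaks per Mb, with an interval from -1.69 to 3.13, and that between X and chromosome 1 was 2.40, with an interval from -0.03 to 4.82. Neither pair was separated. For the other 17 autosomes the interval of the difference from X lay above 0, from 3.09 (0.34 to 5.99) for chromosome 4 to 8.13 (5.71 to 10.3) for chromosome 11. These 19 intervals were not adjusted for their number. They treat blocks of 5 Mb as independent, although peak numbers of bins 5 Mb apart were correlated (Spearman 0.17, pooled over chromosomes), so they may be too narrow. Chromosomes 3 and 11 differed by 7.35 peaks per Mb (4.66 to 9.91).

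**Figure D2:**
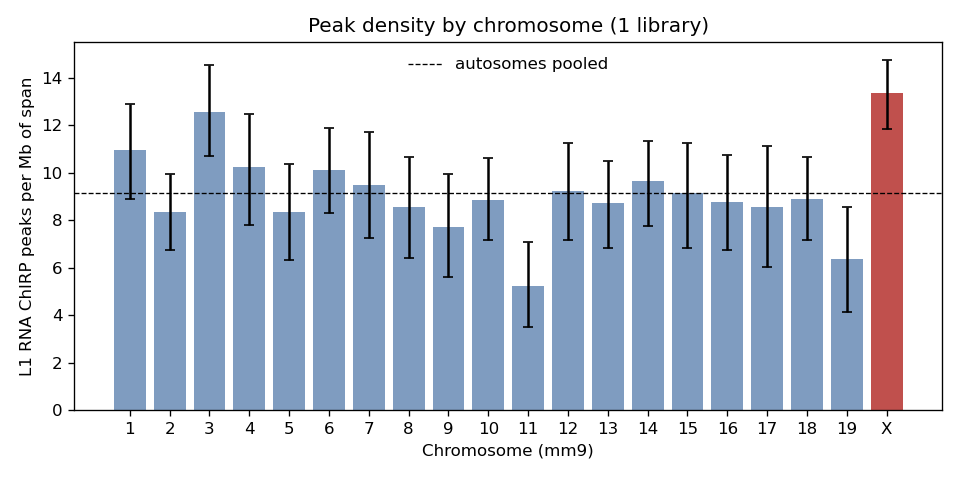
L1 RNA ChIRP peaks per Mb of span (vertical axis) on chromosomes 1 to 19 and X (horizontal axis), with 95% block bootstrap intervals as error bars and the pooled autosomal density, 9.13, as a dashed line. X (red) is the highest at 13.3 peaks per Mb and chromosome 11 the lowest at 5.20.

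Peaks on X were also narrower than those of the pooled autosomes, though not the narrowest of any chromosome. Their median width was 5986 bp, against 6370 bp on the autosomes, a difference of -384 bp (95% bootstrap interval -573 to -195). Chromosomes 7 and 14 had lower medians than X, 5727 and 5838 bp. Peaks wider than 10 kb made up 6.34% of those on X and 12.1% of those on autosomes. By covered bases, X therefore stood less far from the autosomes than by number of peaks: peaks covered 7.93% of its span and 6.01% of the autosomal span, a ratio of 1.32 (95% block interval 1.15 to 1.50). By the same measure chromosome 3 was more covered than X, at 8.63%. Neither the densities nor the widths were adjusted for the number of copies of each chromosome in the cells. Chromosome Y was represented by 40 peaks within a span of 2.76 Mb, or 14.5 per Mb, a span too short for an interval.

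Along the chromosomes the peaks gathered into peak-rich and peak-free regions. Of the 24202 peaks, 40.1% had another peak within 10 kb, against a mean of 18.8% in 1000 random placements, whose highest value was 19.9%. The observed share lay above every placement on 21 of 21 chromosomes. On X the share was 39.4% against a random mean of 25.1%, and on chromosome 11 it was 34.0% against 10.2%. The random mean rises with peak density, so the ratio of the shares, 1.57 on X and 3.34 on chromosome 11, does not rank the chromosomes by clustering. The median gap between neighbouring peaks was 36.0 kb, against 67.3 kb on average in the placements (66.1 to 68.7).

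At the scale of 1 Mb, the densest 10% of bins held 26.8% of the peaks, against 16.9% on average in the placements and 17.3% in the highest. Of 2587 bins, 307 held 20 or more peaks, where random placements gave 4 to 24 such bins, and 285 held none, where they gave 0 to 6. Bins with 20 or more peaks made up 24.2% of the bins of chromosome 3, 18.9% of those of X and 16.9% of those of chromosome 1, but 5.04% of those of chromosome 11. Bins without a peak made up 28.6% of chromosome 11, 23.7% of chromosome 19 and 1.83% of X. Neighbouring bins were alike: after subtraction of each chromosome's mean, the Spearman correlation of peak number across bins was 0.56 for bins 1 Mb apart, 0.39 for 2 Mb, 0.17 for 5 Mb and 0.09 for 10 Mb. The highest values among the placements were 0.06, 0.06, 0.06 and 0.07. On single chromosomes (1 to 19 and X) the 1 Mb correlation ranged from 0.27 to 0.71, whereas the 5 Mb correlation ranged from -0.10 to 0.39 and was above 0 on 15 of 20, the exceptions being chromosomes 6, 10, 17, 18 and 19. At 20 Mb the pooled correlation of 0.04 lay within the range of the placements, -0.07 to 0.06. Bins are not independent replicates, and these are descriptions of 1 library.

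**Figure D3:**
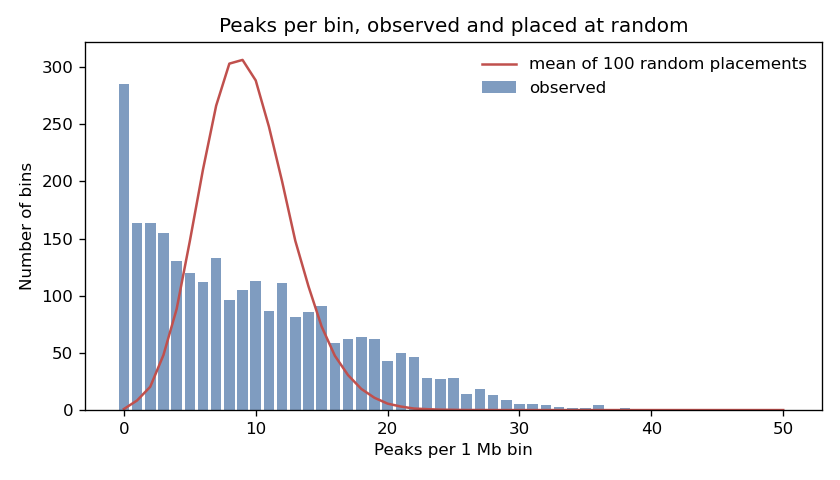
Number of 1 Mb bins (vertical axis) by the number of peaks in the bin (horizontal axis), observed (bars) and as the mean of 100 random placements (line). The observed distribution is wider, with 285 bins without a peak and a highest bin of 43 peaks.

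The 5 bins with the most peaks (mm9) lay on 5 different chromosomes. Chromosome 19 from 39000001 to 40000000 held 43 peaks, which covered 23.8% of the bin. Chromosome 19 as a whole held 6.38 peaks per Mb. Chromosome 7 from 5000001 to 6000000 held 42 peaks, which covered 38.2%. Chromosome 8 from 62000001 to 63000000 held 39 peaks and 28.0% coverage. Chromosome 17 from 55000001 to 56000000 and chromosome 18 from 90000001 to 91000000 each held 38 peaks, with 19.1% and 24.6% coverage. The last peak of chromosome 18 ends within that bin, at 90652169. The highest bin in any of the random placements held 30 peaks. What genes or repeats lie in these bins was not annotated here.

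Peak-rich bins also ran together. The longest run of bins with 20 or more peaks lay on chromosome 3 from 10000001 to 18000000 and held 204 peaks over 8 Mb. Runs of 5 Mb lay on chromosome 1 from 44000001 to 49000000, with 138 peaks, on chromosome 1 from 3000001 to 8000000, with 123 peaks, and on chromosome 3 from 3000001 to 8000000, with 121 peaks. On X no run was longer than 3 Mb, as on X from 73000001 to 76000000, with 77 peaks. In the opposite direction, 277 stretches of over 1 Mb between neighbouring peaks held no peak, where the placements gave 0 to 11. The longest lay on chromosome 4 from 128116539 to 141519634 (13.4 Mb), chromosome 5 from 117061806 to 126358605 (9.30 Mb) and chromosome 8 from 121289369 to 128746161 (7.46 Mb). In the placements the longest such stretch never exceeded 2.56 Mb. Sequence missing from the assembly also holds no peak, and such gaps were not removed.

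**Figure D4:**
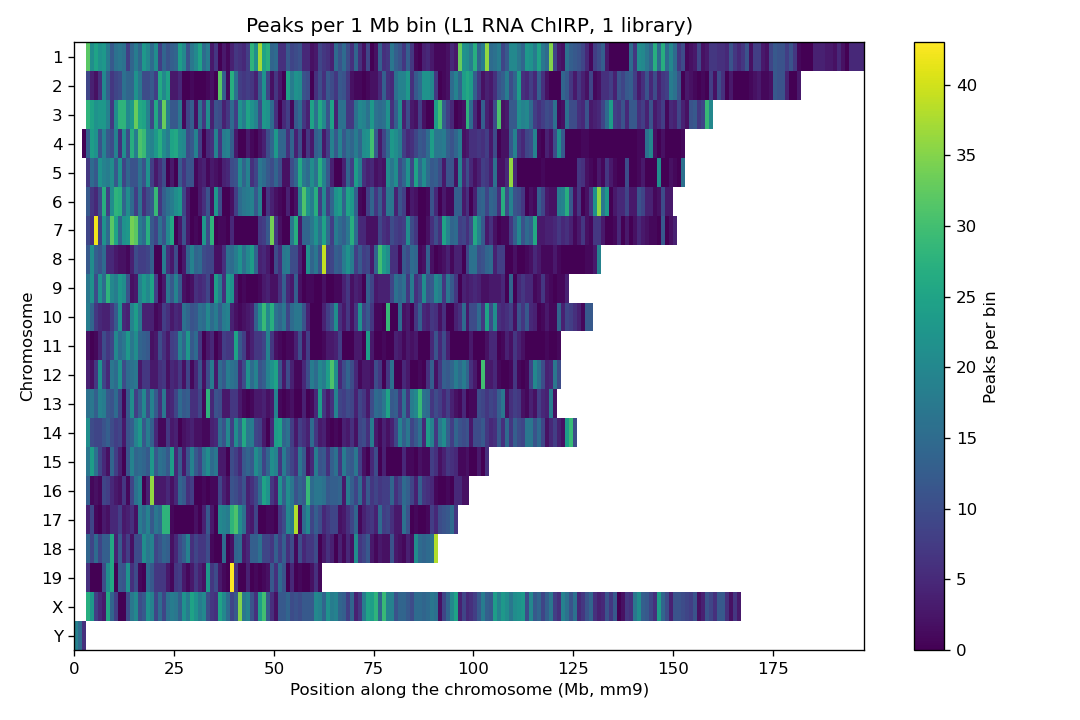
Number of L1 RNA ChIRP peaks per 1 Mb bin (colour) along each chromosome (rows) by position in Mb (horizontal axis, mm9), with white outside the span from the first to the last peak. Dark stretches, such as the peak-free 13.4 Mb on chromosome 4, alternate with bright ones, such as chromosome 3 from 10 to 18 Mb.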

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

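The peaks on unplaced sequence were set apart because they are a signal in data that the comparisons between chromosomes do not use. There were 464 of them, or 1.88% of all peaks (95% binomial interval 1.72 to 2.06), on 10 named unplaced sequences, and their median width was 5774 bp. Most, 385, lay on the unplaced sequence assigned to chromosome Y, which had 6.58 peaks per Mb over a span of 58.5 Mb, against 14.5 per Mb over the 2.76 Mb span of the placed part of chromosome Y. These densities are not like measures, since unplaced pieces have no known order and the placed span is too short for an interval. The other unplaced sequences held between 1 and 34 peaks each. No control library was analysed here, so the level of such peaks without the L1 probes is unknown.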

How the results depend on the processing

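The higher density on X kept its direction in all 6 alternatives, 5 of which were chosen after seeing the data. The ratio of 1.46 became 1.32 by covered bases, 1.31 without bins that hold no peak, 1.61 without the densest 10% of bins of every chromosome, 1.31 for peaks wider than the median and 1.61 for those up to the median width, all outside the counting (binomial) interval of the ratio. It was 1.51 after peaks closer than 5 kb were merged. Every one of these had a block interval above 1. The share of peaks with a near neighbour lay above the highest placement in all 6 alternatives, 3 of them added later: it was 79.5% within 50 kb (highest placement 65.0%) and fell to 29.2% within 10 kb once peaks closer than 1 kb were merged (18.2%). The share in the densest 10% of bins ranged from 21.9% to 29.9% over 6 alternatives, each above its placements. The excess of 6 to 7.5 kb peaks, not planned, ranged from 1.37 to 1.60 over 4 alternatives. Alternatives listed before the data were examined that need a score, a genome or an annotation were not run, and neither was the denominator by chromosome length. No paired analysis was possible because each group has 1 library. Read depth, which sets how many weaker sites pass the caller, is unknown, so the absence of a peak is not evidence of no L1 RNA.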

Other observations

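The 2 ends of the chromosomes differed. Mouse chromosomes are numbered from the centromere, which lies at one end. The first 10 Mb of span, next to the centromere, held 12.6 ± 5.10 peaks per Mb (mean ± SD over 20 chromosomes, 1 to 19 and X), the middle 9.19 ± 1.87 and the last 10 Mb 5.54 ± 3.40. The last 10 Mb was sparser than the middle on 17 of 20 chromosomes, the exceptions being chromosomes 12, 14 and 18, and the first 10 Mb was sparser on 4 of 20, chromosomes 8, 16, 17 and X. Pooled over the 20 chromosomes, density relative to the middle was 1.34 at the first end and 0.59 at the last, where 1000 uniform random placements gave 0.91 to 1.06 and 0.91 to 1.04. Uniform placements ignore the clustering of peaks and so give too narrow a range. In 1000 rotations of the peaks along each chromosome, which keep their spacing and were added after seeing the data, the ratios ranged from 0.62 to 1.39 at the first end, with 2 rotations at or above the observed value, and from 0.63 to 1.37 at the last, with 0 at or below it. Chromosomes 3 and 1 had the densest first ends, with 22.5 and 20.2 peaks per Mb, and the last 10 Mb of chromosome 11 held 0.50 per Mb. This pattern was noticed in the data and no explanation for it was tested.

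The tests of the X and clustering patterns below were written before their results were seen, and those of the width pattern after. All were added after the peak positions had been seen, except the placements within 5 Mb windows, which had been listed before.

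The higher density on X was set against 3 technical explanations. Unsequenced stretches inside the autosomal spans are not the whole cause, since without the bins that hold no peak the ratio was 1.31 (95% block interval 1.17 to 1.47), though it was lower than the 1.46 over all bins. The higher density was not confined to a few very dense regions, since without the densest 10% of bins of every chromosome the ratio was 1.61 (1.42 to 1.80). Those bins were dropped from the autosomes too, so the rise from 1.46 does not measure what dense regions of X contribute. Splitting of broad regions into peaks less than 5 kb apart does not account for the higher density, since the ratio was 1.51 (1.35 to 1.68) after such peaks were merged. Splitting at wider gaps was not tested by this merge. By covered bases, which depend less on splitting, the ratio was 1.32 (1.15 to 1.50), so a part of splitting in the 1.46 is not excluded. The L1 content of X, mappability, and capture of L1 DNA by the probes without its RNA stay open and were not tested, and the design names no biological contrast between chromosomes. Which nucleic acid was sequenced also stays open, so what a peak marks is not settled.

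Clustering was also set against 3 explanations. After peaks closer than 5 kb were merged, 72.9% of the merged peaks still had a neighbour within 50 kb (placements 56.3% to 58.9%). Splitting of broad regions is thus not the whole cause of clustering at 50 kb. This does not decide its part in the 10 kb share, which was not computed after that merge. Regional differences in density can also raise the 50 kb share. With peaks closer than 1 kb merged, the 10 kb share fell from 40.1% to 29.2%, still above the highest placement, 18.2%. With peak-free stretches over 1 Mb cut out, 42.0% had a neighbour within 10 kb (placements 21.9% to 24.1%). The cut itself made neighbours of the peaks on either side of each stretch, which gave the rise from 40.1%. The uncut 40.1% also lay above these placements, which argues against unsequenced stretches as the whole cause. With placements kept inside windows of 5 Mb, the observed 40.1% still lay above them (23.2% to 25.3%), so differences in density between such windows alone do not give it. Clustering of the L1 copies themselves may produce this pattern and was not tested, because no repeat annotation of mm9 was used.

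The mode at 6 to 7.5 kb is close to the length of full-length mouse L1 elements, and a candidate explanation is that many of these peaks each span 1 such element. This could not be decided: 23.7% of peaks fell in the class, but no repeat annotation of mm9 was used. Joining of neighbouring narrower peaks by the caller could not be decided either. Among peaks more than 50 kb from any other the excess over interpolation was 1.60 (95% bootstrap interval 1.46 to 1.78), but distances are measured after calling, so peaks already joined can count as isolated. In peaks within 10 kb of another the excess was 1.37, lower by 0.23 (0.05 to 0.44). Peaks 10 to 50 kb from the nearest had an excess of 1.64 (1.53 to 1.76), close to that of peaks more than 50 kb away. The difference between these classes was not computed. The excess on X, 1.55, and on the autosomes, 1.53, differed by 0.02, with an interval from -0.20 to 0.26. Fragment lengths, the caller's settings and which nucleic acid was sequenced also remain open.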
